A study of Populus trichocarpa and Populus tremula x Populus alba with 8 samples.

How the data were processed

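Gene expression was measured in scraped xylem, the water-conducting tissue that becomes wood, and in scraped phloem, the sugar-conducting tissue on the bark side, of growing poplar trees. Total RNA was labelled with Cy3 and hybridized to 1-colour NimbleGen arrays, 1 sample per array, per the labels' protocols. The 8 arrays fell into 3 groups by the tissue and tree named in the labels. These were 3 arrays of xylem of Populus trichocarpa Nisqually-1, 3 of xylem of a hybrid of Populus tremula and Populus alba, and 2 of phloem of P. trichocarpa. The series' design text calls the xylem and phloem samples biological replicates but does not mention the hybrid. Where replicates came from 1 tree, p-values measure only the spread between these samples, which may be technical.

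The authors deposited 1 scanner table per array, which gives the intensity of every perfect-match probe on a linear scale, per the file headers. These values are not normalized between arrays, and the mismatch column is 0 throughout. The image extraction software is not given in the sources used here. The authors also deposited a table with a value per target and array on the log2 scale, made with RMA per the submitters' processing notes, with the version not given in the sources used here. Across targets, each of its columns correlated with the values of the same array computed here from the scanner tables by 0.986 to 0.987, and its column medians lay between 6.84 and 6.96. Its group differences correlated with those computed here by 0.977 in both comparisons, with slopes of 1.29 for phloem minus xylem and 1.37 for hybrid minus P. trichocarpa xylem. Its scale is therefore log2 without centring of targets and its direction that of intensity, while the background step and other settings of the authors' RMA stay unknown.

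Each array held 194260 poplar probes for 65965 targets and 84 probes for 7 control sequences. A target had 3 probes in 63171 cases, 2 in 1953 and 1 in 841. The background was corrected on all probes with limma's normexp method and an offset of 50, and the control probes were then left out. Intensities were put on the log2 scale and quantile normalized between arrays, and the probes of a target were summarised by median polish with up to 10 passes. Quantile normalization gives all arrays 1 distribution, so a change of most transcripts in 1 direction would not show, and differences are relative to the bulk of targets. A target measured by probes that match 1 tree better than the other can differ between trees without a difference in transcript level.

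The files mark no negative or random probes. The 25th percentile of all targets on an array therefore served as its background level. It is a rank, not a measured blank, so some targets below it may be expressed and some above it may not be. Saturated probes numbered 0 to 5 per array and were kept. The number of arrays limits the precision.

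Groups were compared with limma (lmFit and eBayes) in 1 fit of all 8 arrays, so that the 2 phloem arrays shared the spread estimated from all groups, with 5 residual and 6.87 prior degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all 65965 targets, and a target was called at an adjusted p under 0.05. Calls of at least 2-fold were counted too. The comparisons were phloem minus xylem of P. trichocarpa, hybrid minus P. trichocarpa xylem, and phloem minus hybrid xylem set against the phloem minus P. trichocarpa xylem difference. The last pair shares the phloem arrays, so its chance overlap was simulated 20 times with no effect. On simulated data with 200 of 65965 targets changed, the fit called 56% of 2-fold and 91% of 4-fold changes in the phloem comparison, with 4 false calls. In the hybrid comparison it called 66% and 98%, with 6 false calls. The data had far more calls, 19.1% of targets for phloem and 33.6% for the hybrid, which makes the adjusted threshold less strict. These rates and false calls therefore do not carry over to the data.

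Of the target IDs, 0 matched the gene table of the P. trichocarpa v4.1 assembly, and the files do not pair IDs with gene names. No gene is therefore named, no position in a genome is given, and the 23 gene lists fixed before the data were examined, from secondary wall cellulose synthesis to ribosomal proteins, could not be tested because 0 had a matched target. The rule for targets to print, also fixed before the data were examined, was the 2 IDs with the largest rise and the 2 with the largest fall in each comparison where no names can be had. They also had to be called, to show no overlap between the groups, and to lie above background on every array of the higher group. Array B and array C of P. trichocarpa xylem differed less than any other pair of arrays, and a fit with both averaged as 1 was added after the data were seen.

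No slide or scan date is given in the sources used here, so such batches were not analysed. Alternatives changed the background correction, the normalization, the probe summary, the source of the values, the filter on dim targets, the arrays in the fit, the prior of the spread, the replicate letter as a block and the xylem group, and left out each array in turn. Scaling on the bright control probes, a background level at the median target and a fit without a run of target IDs were added after the data were seen. The work used R 4.3.3, limma 3.58.1, the data.table package (version 1.17.8), matrixStats 1.5.0, Python 3.11.15 and matplotlib 3.10.9.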

Results

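Transcript levels were compared between xylem and phloem of Populus trichocarpa Nisqually-1, the clone behind the poplar reference genome, and between xylem of this clone and xylem of an aspen hybrid of Populus tremula and Populus alba. Xylem of each tree was measured on 3 arrays and phloem of P. trichocarpa on 2. Raw probe signal differed between groups. The 75th percentile of intensity was 628 to 726 on the P. trichocarpa xylem arrays, 465 to 583 on the hybrid arrays and 822 to 1076 on the phloem arrays. The signal range was narrowest in the hybrid, where the 75th percentile was 4.23 to 4.86 times the 5th, against 6.41 to 8.07 times in P. trichocarpa xylem and 6.85 to 7.80 times in phloem.

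Both tree and tissue separated the arrays. Across targets, which are not independent replicates, normalized log2 values of replicates correlated by 0.974 to 0.995 in P. trichocarpa xylem, by 0.982 to 0.988 in hybrid xylem and by 0.976 in phloem. Xylem of both trees correlated by 0.882 to 0.914, about as much as phloem and xylem of P. trichocarpa (0.892 to 0.904). Phloem of P. trichocarpa and xylem of the hybrid, which differ in both, correlated least (0.833 to 0.851). The first principal component held 55.2% of the variance and placed the hybrid arrays opposite the phloem arrays. The second held 31.6% and placed P. trichocarpa xylem apart from the other two groups. Within P. trichocarpa xylem, arrays B and C differed by an SD of 0.16 (log2) over targets, while array A differed from them by 0.35 and 0.36.

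**Figure D1:**
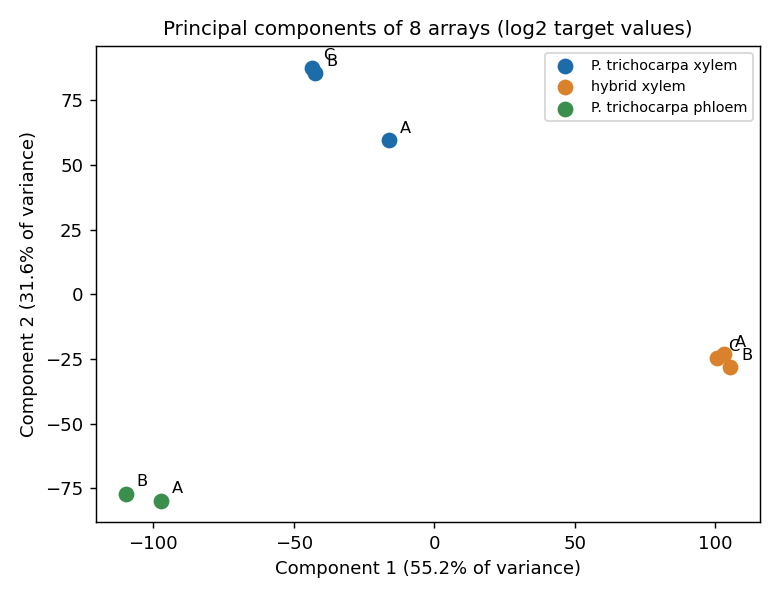
Scores of the 8 arrays on the first and second principal components of log2 target values, with each point an array, its colour the group and its letter the replicate. The axes carry 55.2% and 31.6% of the variance, the 3 groups do not overlap, and array A of P. trichocarpa xylem lies apart from arrays B and C.

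Phloem and xylem of P. trichocarpa differed in 12597 of 65965 targets (19.1%; limma, adjusted p under 0.05), of which 6768 were higher and 5829 lower in phloem. At least 2-fold differences were found in 2724 targets higher and 2697 lower in phloem. At 4-fold or more, 672 were higher and 929 lower, and at 16-fold or more, 81 were higher and 149 lower. Counts by fold depended on the processing, since the authors' RMA table gave 4189 targets higher and 3843 lower in phloem at 2-fold or more.

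The target with the largest rise in phloem was TREE0002S00007888, with a log2 signal of 14.80 ± 0.27 (SD, n = 2) in phloem and 8.86 ± 0.16 (SD, n = 3) in xylem. This is a 61.6-fold difference (log2 5.94, SE 0.20, limma adjusted p = 1.41e-09). It was also low in hybrid xylem, at 7.51 ± 0.33 (SD, n = 3). TREE0002S00038309 was 43.6-fold higher in phloem (log2 5.45, SE 0.14, limma adjusted p = 7.19e-10), with 13.66 ± 0.13 (SD, n = 2) against 8.21 ± 0.01 (SD, n = 3), and its 3 probes rose by 5.39, 5.93 and 3.18. On the xylem side, TREE0002S00000629 fell by 6.65 on the log2 scale in phloem, or 100.1-fold (SE 0.15, limma adjusted p = 7.19e-10). Its signal was 14.24 ± 0.17 (SD, n = 3) in P. trichocarpa xylem and 14.001 ± 0.07 (SD, n = 3) in hybrid xylem against 7.59 ± 0.16 (SD, n = 2) in phloem. TREE0002S00002978 fell by 6.41 in phloem, or 85.1-fold (SE 0.20, limma adjusted p = 1.21e-09), from 13.69 ± 0.42 (SD, n = 3) to 7.28 ± 0.05 (SD, n = 2). This target stood at 11.13 ± 0.07 (SD, n = 3) in hybrid xylem, between both P. trichocarpa tissues.

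**Figure D2:**
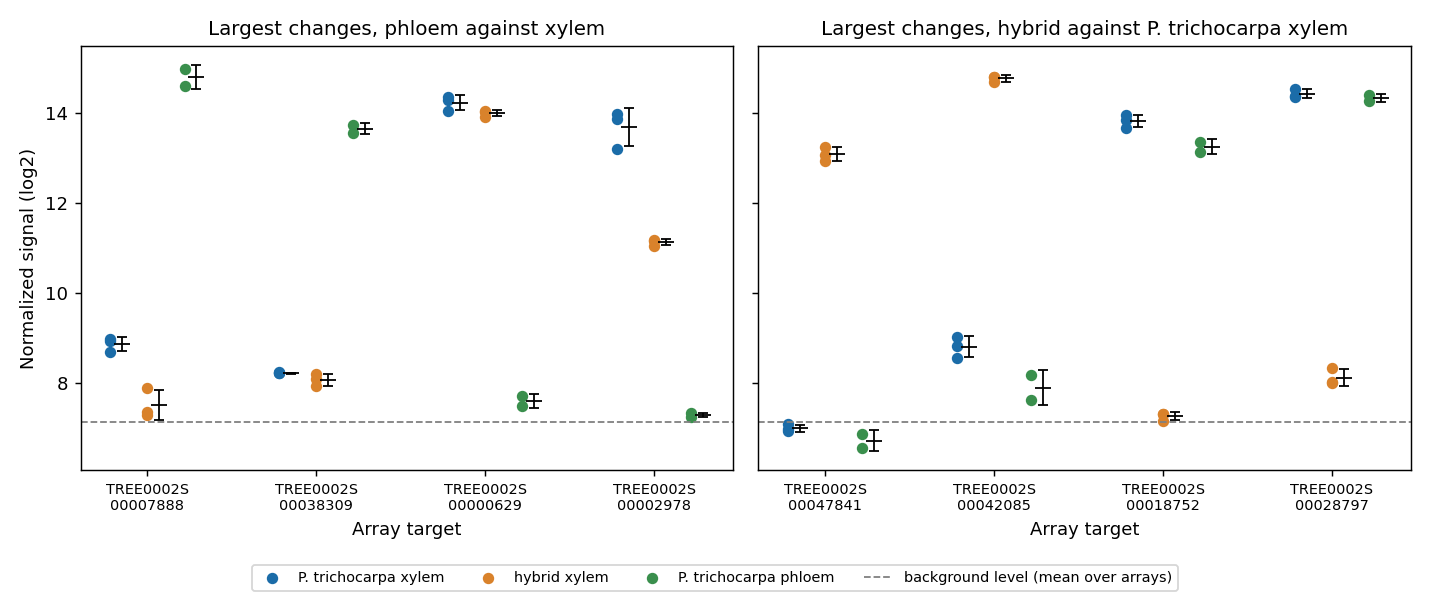
Normalized log2 signal of the targets with the largest changes, phloem against xylem on the left and hybrid against P. trichocarpa xylem on the right, with each point an array, colours for the groups, black marks for the mean and SD of a group, and a dashed line for the mean background level. TREE0002S00000629 is high in xylem of both trees (14.24 and 14.001) and low in phloem (7.59), while TREE0002S00028797 is high in both P. trichocarpa tissues (14.43 and 14.34) and low in the hybrid (8.11).

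Signal above background was found on all 8 arrays for 41564 targets and on no array for 9915. On both phloem arrays but on no xylem array of either tree it was found for 295 targets, and 90 of these were called at least 2-fold higher against each xylem group. The reverse, signal on all 6 xylem arrays and on no phloem array, was found for 253 targets, of which 56 were called at least 2-fold lower against each xylem group. With the median target as the background level, set after the data were seen, these classes held 24805, 24679, 783 and 441 targets.

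The direction of calls between tissues was relative to the scaling. Higher targets made up 53.7% of calls after quantile normalization and 41.7% after median scaling, while scaling on the bright control probes, added after the data were seen, moved the median of all targets from 0.02 to 0.51 and called 25391 targets, 89.4% of them higher in phloem.

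Xylem of the hybrid differed from xylem of P. trichocarpa in 22148 targets (33.6%; limma, adjusted p under 0.05), with 10934 higher and 11214 lower in the hybrid. Among differences of at least 2-fold the balance shifted to lower signal in the hybrid, with 1925 targets higher and 4362 lower. At 4-fold or more, 458 were higher and 936 lower, and at 16-fold or more, 34 were higher and 49 lower. Signal above background on every P. trichocarpa array of either tissue and on no hybrid array was found for 640 targets, of which 221 were called at least 2-fold lower in the hybrid than in either. Only the hybrid arrays were all above background for 238 targets with no P. trichocarpa array above it, and 77 of these were called at least 2-fold higher than in either. With the median target as background, these classes held 1270 and 610 targets.

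TREE0002S00047841 had the largest rise in the hybrid in the main setting, 68.8-fold (log2 6.10, SE 0.14, limma adjusted p = 2.7e-10), from 6.98 ± 0.08 (SD, n = 3) to 13.09 ± 0.15 (SD, n = 3). It was above background on 1 of 3 P. trichocarpa xylem arrays, and with the background level in place of lower values the difference was 63.97-fold. Its phloem signal was 6.70 ± 0.23 (SD, n = 2). TREE0002S00042085 was 62.997-fold higher in the hybrid (log2 5.98, SE 0.16, limma adjusted p = 8.05e-10), at 14.77 ± 0.07 (SD, n = 3) against 8.80 ± 0.23 (SD, n = 3), but its 3 probes rose by 1.54, 6.48 and 5.99. Its phloem signal was 7.89 ± 0.38 (SD, n = 2). Without background correction TREE0002S00042085 rose by 5.93 and TREE0002S00047841 by 5.82, so their order depends on the processing. TREE0002S00018752 fell by 6.58 in the hybrid, or 95.6-fold (SE 0.13, limma adjusted p = 1.99e-10), from 13.83 ± 0.14 (SD, n = 3) to 7.25 ± 0.09 (SD, n = 3), where 2 of 3 hybrid arrays were above background. With the background level in place of the lower value the difference was 95.1-fold. Phloem of P. trichocarpa held it at 13.25 ± 0.17 (SD, n = 2). TREE0002S00028797, measured by 1 probe, fell by 6.32, or 80.0-fold (SE 0.13, limma adjusted p = 2.02e-10), from 14.43 ± 0.10 (SD, n = 3) to 8.11 ± 0.19 (SD, n = 3), and phloem held it at 14.34 ± 0.09 (SD, n = 2). For each of these 4 targets the mean of phloem lay within 1 log2 unit of that of P. trichocarpa xylem.

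All 3 probes of a target passed 2-fold less often for targets called lower in the hybrid than for those called lower in phloem. Outside the run of IDs described next, and among targets with 3 probes, all 3 were at least 2-fold lower for 30.8% of the 4043 targets called at least 2-fold lower in the hybrid. The share was 56.1% of the 2001 targets with 3 probes called at least 2-fold lower in phloem. For targets called at least 2-fold higher outside the run, the shares with all 3 probes higher were 28.3% in the hybrid and 43.8% in phloem. Within the run the shares were 26.5% and 49.6% for targets called lower, and 32.3% and 29.2% for targets called higher. These shares are not matched on the size of the change, and with a smaller change all 3 probes pass 2-fold less easily. Over all targets, 929 of 2697 falls in phloem reached 4-fold, against 936 of 4362 falls in the hybrid.

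The hybrid difference also followed the target IDs. Targets were grouped into 70 bins of 1000 IDs, and bright targets, those above the 75th percentile of mean signal, were compared by bin. In 9 neighbouring bins, IDs from 42000 up to 51000, chosen after the bin values were seen, the median hybrid minus P. trichocarpa difference was 0.31 to 0.50 in every bin. In the first 42 bins it ran from -0.48 to 0.37 and was below 0 in 37. In the run of 9 bins, 1144 targets were at least 2-fold higher in the hybrid and 141 lower, against 781 higher and 4221 lower outside it. The direction within the run depended on the scaling, since 89.0% of these calls were higher in the hybrid after quantile normalization (15.6% outside) and 41.7% after scaling on the bright control probes (2.00% outside). Both targets with the largest rise in the hybrid lie in this run. The run holds 13.6% of all targets, but 99 of the 238 targets above background on the hybrid arrays alone. It holds 10 of the 640 targets above background on every P. trichocarpa array and on no hybrid array. The next 2 bins after the run lay at 0.16 and -0.34. The 17 bins from ID 53000 on had medians of 0.06 to 0.77, and 6 of them reached the range of the run or lay above it. They held 15 to 111 bright targets each, 2 of them under 20, and without those 2 the highest median was 0.49. For phloem minus xylem, the median of bright targets in the run lay at -0.08 relative to the others, and 318 targets of the run were at least 2-fold higher and 613 lower in phloem.

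**Figure D3:**
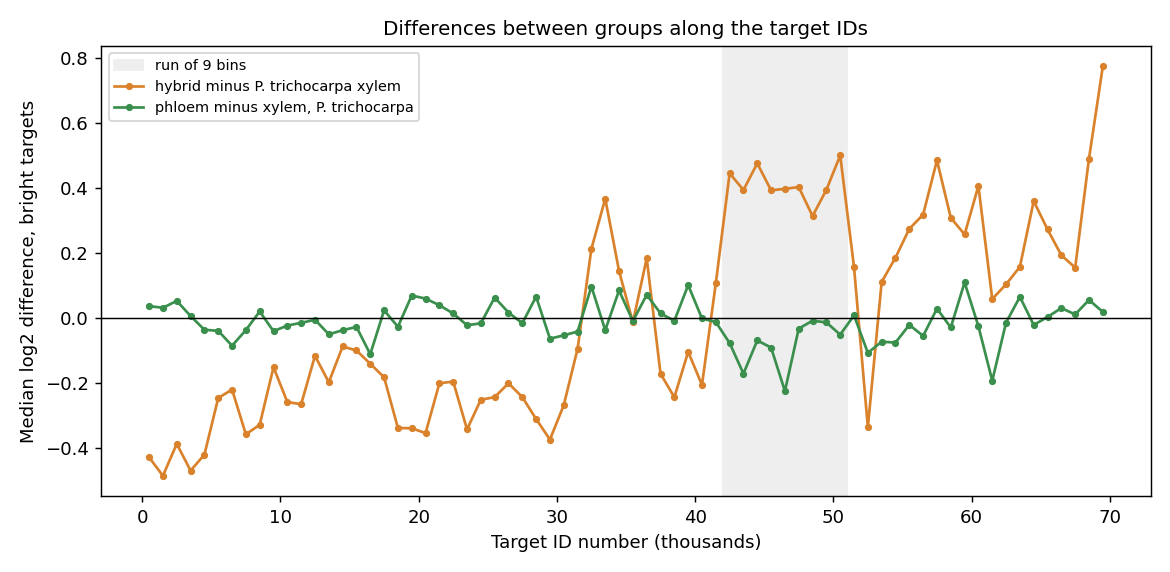
Median log2 difference of bright targets in bins of 1000 target IDs, for hybrid minus P. trichocarpa xylem and for phloem minus xylem of P. trichocarpa, with each point a bin and the run of 9 bins shaded. The hybrid difference lies between 0.31 and 0.50 throughout the shaded run and below 0 in 37 of the first 42 bins.

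The hybrid count moved with single arrays, to 14347 targets without P. trichocarpa xylem array B, 14542 without C and 27446 without A, to 15970 to 19059 without a hybrid array, and to 14507 with B and C, which could be technical repeats, averaged as 1. Among all calls 49.4% were higher in the hybrid after quantile normalization, 35.1% after cyclic loess and 6.34% after scaling on the bright control probes, which moved the median of all targets from 0.10 to -0.23 and called 11511 targets at least 2-fold.

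The tissue difference was then set against both xylem groups, to see whether it depended on the tree the xylem came from. Phloem differed from hybrid xylem in 21060 targets (limma, adjusted p under 0.05), and 7861 targets were called in 1 direction against both xylem groups, 62.4% of those called within P. trichocarpa. Of these, 5043 were higher and 2818 lower in phloem, and a further 827 were called in opposite directions. At least 2-fold against both groups, 2069 were higher and 1238 lower in phloem. The run of IDs, chosen for its high hybrid signal, held 169 of the higher and 508 of the lower targets, which leaves 1900 higher and 730 lower outside it.

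Independent lists of these sizes would share 1164.5 higher and 858 lower targets. Simulated data with no effect in any group shared 0.1 on average, a low count set by the design, since hardly any target is called there. The log2 differences correlated by 0.621 across targets against 0.599 in the simulation, with a covariance of 0.343 against 0.0184, a difference of 0.325. The 2 differences had 1 sign in 63.9% of all targets, below the 70.4% of the simulation. The simulated values hold only the noise of the arrays, including the phloem arrays that both comparisons share. Neither benchmark holds a real phloem difference, which would enter both comparisons. How much of the overlap reflects likeness between xylem of both trees is therefore not shown. Splitting the 2 phloem arrays between the comparisons would leave 1 for each, and this was not done. Scaling on the bright control probes raised the shared count to 22143, with 96.7% of them higher in phloem against 64.2% after quantile normalization.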

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

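The control sequences, left out of every comparison except the added scaling on them, stood higher over the median poplar probe on the hybrid arrays than on the P. trichocarpa xylem arrays. The 6 bright control sequences lay 4.36 ± 0.07 (log2, SD, n = 3) above it in the hybrid and 3.96 ± 0.30 (SD, n = 3) in P. trichocarpa xylem, a difference of 0.40 (two-sided exact permutation p = 0.1, the smallest that 3 arrays against 3 can give). Without array A of P. trichocarpa xylem the difference was 0.22, and without any other xylem array it was 0.36 to 0.50. All 6 sequences were higher in the hybrid. In phloem they lay 3.36 ± 0.18 (SD, n = 2) above the median probe, which is -0.60 relative to P. trichocarpa xylem (exact permutation p = 0.2, where the smallest possible is 0.1). The test was chosen after the data were seen, and the files do not say whether the control RNA was added in equal amounts.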

How the results depend on the processing

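Alternatives on control-probe scaling, on arrays B and C averaged, on the run of IDs and on the background level were chosen after the data were seen. Of 258 alternative values, leaving out those of the probe chosen by its outcome, 241 kept their direction and side of the threshold, or stayed within 1.5 times of a count. Most of these values belong to the 8 printed targets, picked from the same data for their large changes, so the share says little of stability. Counts were compared by their total alone. Control-probe scaling thus kept the hybrid count, at 20100, though 6.34% of its calls were higher against 49.4%. Of these calls, 12439 were shared with the main setting. All 8 printed targets kept direction and call in every other setting that held them, with log2 changes between 4.83 and 6.31 for the rises in phloem, -8.15 and -5.73 for the falls in phloem, 4.67 and 7.88 for the rises in the hybrid, and -8.51 and -6.16 for the falls in the hybrid.

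With hybrid xylem in place of P. trichocarpa xylem, phloem differed in 21060 targets, 8654 of them at least 2-fold. Control-probe scaling gave 25391 and 9206 for phloem, 11511 at least 2-fold for the hybrid and 22143 shared targets. The authors' RMA table gave 11209 at least 2-fold in the hybrid. Leaving out each array in turn gave hybrid counts from 14347 (without P. trichocarpa xylem array B) to 27446 (without array A), and averaging B and C gave 14507. Where a phloem array was left out, the other was assumed to vary like the other groups. With the median target as background, all 7 classes by signal above background moved by over 1.5 times. The cause of these changes was not tested.

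Among calls of at least 2-fold, the share higher in phloem was 50.2% after quantile normalization, 39.7% after median scaling and 81.2% after control-probe scaling. The share higher in the hybrid was 30.6%, 17.7% and 5.96%. Taking for each target the probe with the highest hybrid minus P. trichocarpa difference, an upper bound that selects on the outcome and says nothing of stability, gave 82.8%, and 84.4% of all calls.

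Whether arrays with 1 replicate letter share a tree or a batch is not given in the sources used here. Deviations of arrays with 1 letter correlated by -0.13 to 0.29, above 0.1 in 3 of 7 pairs. Those of arrays with different letters correlated by -0.29 to 0.23, above 0.1 in 3 of 14 pairs. Deviations were taken from the group mean, so those of the 2 phloem arrays mirror each other. P. trichocarpa xylem A, for example, correlated by 0.287 with phloem A and by -0.287 with phloem B. The pairs are therefore not separate evidence, and no chance level was computed for these counts. The highest value was that of P. trichocarpa xylem A with phloem A, and 5 of 8 arrays lay nearest their own letter. A pairing by letter is therefore neither shown nor excluded. With the letter as a replicate block, 12428 targets were called for phloem (5408 at least 2-fold), 23526 for the hybrid (6328) and 7934 shared, and no printed target changed its call. Gene list alternatives were not run, since no list could be matched. Signal near background limits the low side of a fold.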

Other observations

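The tests on normalization, on the probes of targets in the run and on the probes of targets called higher outside it were chosen after related results had been seen; the others were set before their results. The run of IDs itself was chosen after its values had been seen.

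Targets in the run of IDs from 42000 up to 51000 were also counted by direction in the tissue comparison, with no test of the difference from other targets. Within P. trichocarpa, 318 of them were at least 2-fold higher and 613 at least 2-fold lower in phloem (34.2% higher), against 2406 and 2084 outside the run (53.6% higher). The share higher stayed lower in the run than outside under control-probe scaling, at 69.2% against 83.1%, and under median scaling, at 23.7% against 43.2%.

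Higher hybrid signal in the run of IDs, relative to other targets, is not accounted for by brightness alone or by the normalizations tried. With targets matched on mean signal the run stood 0.35 above the others (95% bootstrap interval 0.34 to 0.37), and at least 0.33 (0.32 to 0.34) under 5 other settings. Unmatched, it stood 0.20 above them in the main setting. The smallest unmatched values under the other settings were 0.11, after median scaling and after control-probe scaling. The normalization test was changed from unmatched to matched after these unmatched values were seen. Median scaling and control-probe scaling shift each array by a constant, so they could show only whether quantile normalization had created the difference. The setting without background correction kept the quantile normalization, so it tested the background step alone. The run was chosen for high values of this difference, which the intervals do not allow for. Place on the array does not account for it either, since the run stood higher in all 64 tiles of the array surface, by 0.20 in the median tile. A candidate explanation is that probes match 1 genome better than the other. Among targets outside the run called at least 2-fold lower, probes of 1 target disagreed 1.82 times as much between trees as between tissues (1.70 to 1.90). Among those called higher the ratio was 1.39 (1.27 to 1.51). These values concern targets outside the run and do not bear directly on the higher signal within it. In the run the ratio was 1.46 (1.08 to 1.79) for targets called lower and 1.12 (0.969 to 1.27) for those called higher. The last interval includes 1, so for targets higher in the run the ratio cannot tell. The hypothesis that their probes were drawn from sequence closer to the hybrid's parents was not tested. Probe sequences, which would bear on it, were not analysed here, and a difference in expression between the trees stays open, untested.

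Of the 10 splits of the 6 xylem arrays into 3 and 3, only the real one (1 split) called as many targets, with 22148 (limma; 29244 at an unadjusted p under 0.05), and the highest other split called 0 (6338 unadjusted). With 10 splits the share cannot fall under 0.1. Every other split places both trees on each side, so the difference between trees adds to its spread and lowers its calls. The splits therefore repeat the separation of the groups already seen and say nothing of the run of IDs.

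Array A of P. trichocarpa xylem stood apart from arrays B and C. It correlated with the hybrid arrays by 0.909 to 0.914, against 0.882 to 0.892 for B and C. Its raw signal range was narrower, with a 75th percentile 6.41 times the 5th, against 7.89 times for B and 8.07 times for C. Whether this range accounts for its place was not tested. RNA of the hybrid on array A would have raised 57 targets that are dim on B and C and bright in the hybrid. They rose by 0.0149 over matched dim targets (95% bootstrap interval -0.0638 to 0.104). Phloem RNA would have raised 73 targets bright in phloem alone, and they stood at -0.0543 (-0.103 to -0.0137), so neither accounts for the difference. The same measure was positive for both other arrays, at 0.0702 for B and 0.161 for C with hybrid targets, and at 0.0937 and 0.125 with phloem targets. Array A lay below B and C in both. Noise of single probes cannot be told apart from a difference between samples, since deviations of array A correlated by 0.190 between probes of 1 target, against 0.121 for B and 0.168 for C. No biological explanation was tested.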
